A study of Mus musculus with 36 samples.

How the data were processed

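ChIP-seq libraries came from livers of 16 mice, 8 C57BL/6J and 8 129S1/SvImJ, fed chow or a high-fat diet (HFD), 4 mice per group. Per the labels' protocols, frozen liver was fixed with formaldehyde and sonicated, and libraries were made by ChIPmentation, in which the Tn5 transposase adds adapters while the chromatin is on the beads. There were 16 H3K27ac, 8 TCF7L2 and 8 CTCF libraries, and each library of a group came from a separate mouse, per the mouse identifiers in the labels. The 8 TCF7L2 and CTCF mice were among the 16 H3K27ac mice. The 4 input libraries were not analysed here. The sex and age of the mice and the time on diet are not given in the sources used here.

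The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.4b, SAMtools 1.9, Picard 2.8.13, MACS2 2.2.7.1, bedtools 2.27.1, deepTools 3.4.2 and the genome build mm10, without the role or order of the tools. How reads of 129S1/SvImJ were aligned, how duplicates were treated, and whether Tn5 cut sites were shifted are not given in the sources used here. The authors deposited whole-number read counts per region for H3K27ac (121119 regions) and TCF7L2 (13571 regions), not normalized. The counts of the series tables and of the library files differed at 0 places. The counted H3K27ac regions are the merged peaks of the 4 consensus lists, one per group, which also were deposited. H3K27ac regions had a median width of 345 bp (49 to 42913) and TCF7L2 regions of 200 bp (200 to 975). Peak lists per library were deposited as positions with no score, so peaks could not be ranked or filtered. CTCF was used as peak lists only, after repeated entries within a list had been removed.

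Regions were given to the nearest protein-coding gene within 100 kb, from gene spans of a table of the same build (GRCm38, 21887 genes). The table has no strand, so distances were taken to the gene span and not to the transcription start as first planned, and a region inside a gene may be a promoter, exon or intron. Of the H3K27ac regions, 59.5% lay inside a gene span, 12.3% within 1 kb of its end, 22.3% farther out within 100 kb and 5.92% beyond; for TCF7L2 these were 47.5%, 12.8%, 30.9% and 8.87%. The nearest gene is a name for a region and need not be the gene it regulates. No reference genome was used, so motifs were not searched and no sequence is given.

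Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with TMM scaling, the tool's filter on low counts by group, a model of 4 group means per mark and Benjamini-Hochberg adjustment at 0.05. After the filter 111812 H3K27ac and 11318 TCF7L2 regions were tested. The contrasts were 129S1/SvImJ minus C57BL/6J averaged over diets, HFD minus chow averaged over strains and within each strain, and the difference of the diet effect between strains. Fold changes are the fitted ones. CPM values are the deposited counts scaled to the reads in tested regions with TMM. Reads in counted regions ranged from 15318987 to 24579005 for H3K27ac and from 139287 to 434898 for TCF7L2; they are not the sequencing depth. Against a group with all libraries at 0, folds were computed against 3 reads over the group, and with 1 to 3 reads as a ratio with a 95% counting interval. Intervals and floors cover counting error only.

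The 25 gene lists, the tests, the alternatives and the rule for named regions were written before the data were examined. The lists cover fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, fatty acid oxidation and PPARa targets, lipid droplet and lipid uptake, bile acid synthesis and transport, gluconeogenesis and insulin response, xenobiotic metabolism, oxidative stress response, unfolded protein response, circadian clock, Wnt and TCF7L2 targets, pericentral, periportal and identity genes of hepatocytes, acute phase response, macrophage and Kupffer cell, lymphocyte, neutrophil, stellate cell and fibrosis, sinusoidal endothelial cell, cholangiocyte, erythroid, cell cycle, and male- and female-biased liver genes. Of 643 list entries 641 had a gene span. Lists with at least 5 regions were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between regions, and again with an estimated correlation. The mean log2 CPM of each list was also compared between diets by an exact permutation of diet within strain (4900 assignments, two-sided), adjusted over the 25 lists; this test was added after the camera results had been seen.

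Named regions follow the fixed rule. Part a took the first 6 higher and 6 lower by p, 1 per gene, among called regions in which the libraries of the compared levels did not overlap (no such condition for the difference of the diet effect). Part b took genes of each list with a called region, part c the regions nearest to Tcf7l2, Axin2, Glul, Lgr5, Cyp2e1 and Nnt, and part d the 3 called regions with the largest fold each way for strain. Of part b, the text names the first 2 genes by p of each list past camera's threshold, and for TCF7L2, where none passed, the first gene of each list. That narrowing was set after values had been seen, as was the choice to count all regions of the part c genes and to name further called ones for diet. Regions near members of multigene families are reported as uncertain.

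CTCF and H3K27ac peak lists were compared with bedtools 2.31.1 by overlap of at least 1 bp, with exact permutation tests over the splits of libraries (two-sided). Strain log2 differences of TCF7L2 regions and overlapping H3K27ac regions were compared by Spearman correlation across regions, which are not independent, without a p-value. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. Replicates of a group were compared by chi-square per degree of freedom, which was 2.22 to 8.14 in 24 H3K27ac pairs and 1.38 to 1.49 in 4 TCF7L2 pairs, so no pair was within sampling noise.

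The tests were tried on simulated counts in which 200 of 111812 H3K27ac or 11318 TCF7L2 regions were changed. Of changes of 1.5, 2 and 4-fold, 22.4, 68.7 and 98.5% were recovered for H3K27ac strain, 32.8, 76.1 and 100% for H3K27ac diet, 7.46, 44.8 and 92.4% for diet in C57BL/6J and 7.46, 29.9 and 89.4% for diet in 129S1/SvImJ. For TCF7L2 the shares were 13.4, 46.3 and 95.5% for strain and 2.99, 41.8 and 87.9% for diet. Unchanged regions called falsely numbered 9, 4, 2 and 6 in the H3K27ac comparisons, in the order given, and 4 and 0 for TCF7L2 strain and diet. The 200 changed regions are fewer than the real calls for strain and for H3K27ac diet, so recovery there may differ. A simulated shifted list was called in both marks, with 1 other list of 25 called for H3K27ac and 0 of 21 for TCF7L2. Simulated regions were drawn independently of each other, while the estimated correlation in the real H3K27ac macrophage list was 0.2665. The simulation therefore does not test camera at the preset correlation where regions of a list vary together. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no TMM scaling, loess offsets, no filter, a replicate block, fits without the TCF7L2 mice or of a single strain, a gene distance of 10 kb, stricter overlaps and each library left out.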

Results

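Livers of 16 mice were profiled by ChIP-seq. The mice were 8 of the strain C57BL/6J and 8 of the strain 129S1/SvImJ, and in each strain 4 mice ate chow and 4 ate a high-fat diet (HFD). Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was measured in all 16 mice. TCF7L2, a transcription factor at the end of the Wnt pathway, and CTCF, a zinc-finger protein found at chromatin loop anchors, were measured in 8 of the same mice, 2 per group. The design addresses how genotype and diet are related to TCF7L2 binding and chromatin state in the liver, so each mark was compared between strains, between diets, and for the difference of the diet effect between strains. H3K27ac reads were counted over 121119 regions, with 15318987 to 24579005 reads per library (mean 18619007 ± 2749532, SD, n = 16). TCF7L2 reads were counted over 13571 regions, with 139287 to 434898 reads per library (mean 282152 ± 101514, SD, n = 8), and replicate 1 was the shallower library in each of the 4 groups. CTCF was given as peak positions, 51589 to 71339 per library, and its read depth is unknown. Positions refer to the mouse genome mm10 and are 1-based.

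Strain separated the libraries of both counted marks along the first principal component. For H3K27ac this component held 48.6% of the variance, with all 8 C57BL/6J libraries between -160.3 and -112 and all 8 129S1/SvImJ libraries between 116 and 138. The second component held 12.6%, and the 8 chow libraries lay below 0 and the 8 HFD libraries above it in both strains. For TCF7L2 the first component held 43.5%. Its second component, with 15.4%, set C57BL/6J HFD replicate 1, the shallowest TCF7L2 library, at 47.6 and the other libraries between -20.2 and 10.1.

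**Figure D1:**
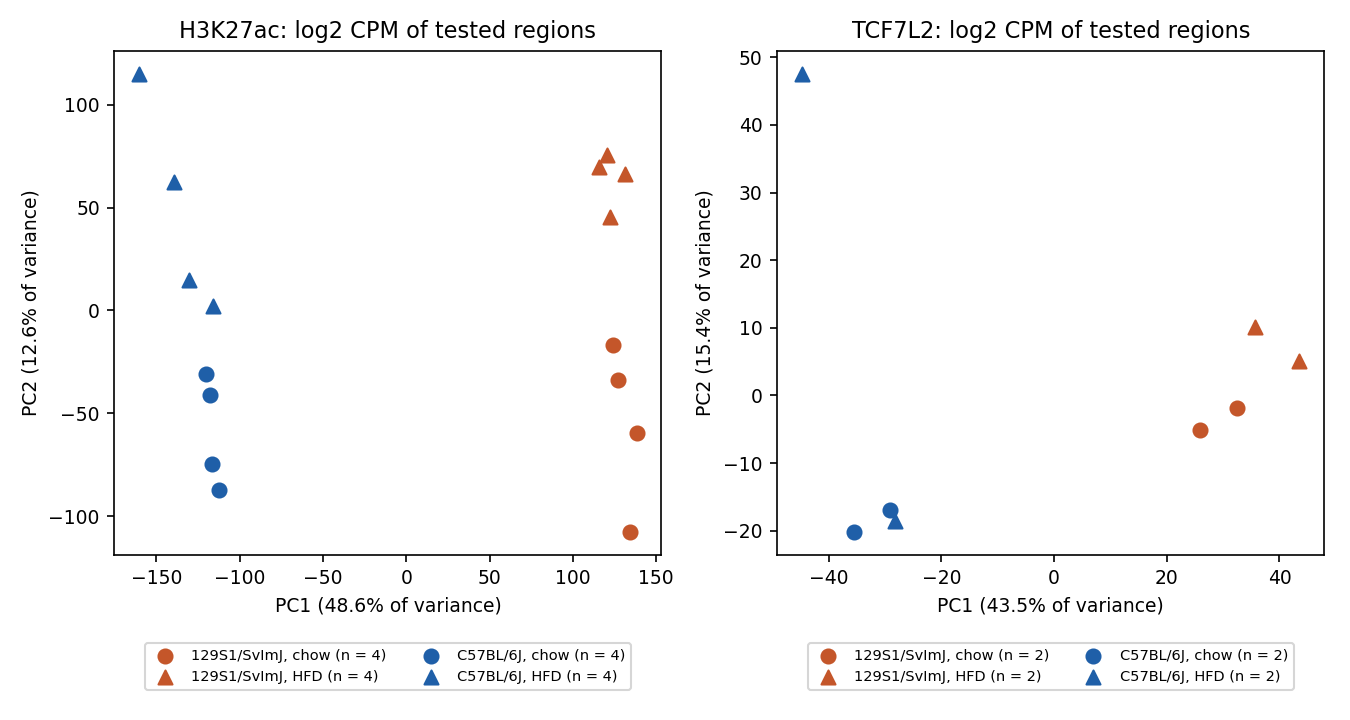
Principal components 1 and 2 of log2 depth-scaled read counts (CPM) over tested regions for H3K27ac (16 libraries) and TCF7L2 (8 libraries), with 1 point per library, colour for strain and shape for diet. Strain parts the libraries on component 1 of both marks, which holds 48.6% and 43.5% of the variance, and diet parts the H3K27ac libraries on component 2.

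On HFD, H3K27ac fell across the genes of cholesterol synthesis and rose near the sterol exporter genes Abcg5 and Abca1. The region 394 bp outside Sqle, which encodes squalene epoxidase (chromosome 15, 59314102 to 59314698), fell from 8.16 ± 2.22 CPM on chow to 0.384 ± 0.277 on HFD (SD, n = 8 each), a fitted change of 23.3-fold. Lower signal was also found at Fdft1 (squalene synthase, 9.63-fold lower), Idi1 (isopentenyl diphosphate isomerase, 7.08-fold), Srebf2 (the transcription factor of the pathway, 5.77-fold), Cyp51 (lanosterol demethylase, 5.75-fold) and Hmgcs1 (HMG-CoA synthase, 3.95-fold). The clearest rise was in a region that begins inside Dync2li1 (chromosome 17, 84646207 to 84658740), from 25.3 ± 7.88 to 211 ± 56.5 CPM, or 8.35-fold (SD, n = 8 each). That region reaches into Abcg5, named here after its value was seen, which with Abcg8 forms the sterol exporter of bile canaliculi. A region 57222 bp from Abca1, a cholesterol exporter (chromosome 4, 53217210 to 53219923), rose 2.90-fold, from 9.63 ± 1.33 to 27.9 ± 4.55 CPM.

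The other leading rises were at Cers3, a ceramide synthase (chromosome 7, 66800390 to 66801857; 3.10-fold), Dysf, a membrane repair protein (chromosome 6, 84042499 to 84044356; 2.68-fold), Adam11 (chromosome 11, 102751154 to 102753578; 4.02-fold) and the epidermal growth factor family gene Btc (chromosome 5, 91266281 to 91267568; 5.24-fold). Log2 changes with standard errors were -4.54 ± 0.24 at Sqle, -3.27 ± 0.20 at Fdft1 (chromosome 14, 63170531 to 63178005), -2.83 ± 0.17 at Idi1 (chromosome 13, 8884534 to 8887631), -2.53 ± 0.13 at Srebf2 (chromosome 15, 82147804 to 82148946), -2.52 ± 0.16 at Cyp51 (chromosome 5, 4102289 to 4105755), -1.98 ± 0.14 at Hmgcs1 (chromosome 13, 119688447 to 119690379) and 3.06 ± 0.16 at Dync2li1. These 12 regions were chosen by a rule under which the 8 HFD libraries did not overlap the 8 chow libraries. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, their adjusted p ran from 3.40e-12 at Dync2li1 to 2.27e-08 at Btc. Over all tested regions, the same test called 6148 higher and 6092 lower on HFD among 111812, or 10.9%. Without the between-library (TMM) scaling the split was 7942 higher and 4652 lower, and the median log2 change of all regions was 0.09 in place of 0.03. In a fit without the 8 mice that also gave TCF7L2 libraries, 5970 regions were called.

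**Figure D2:**
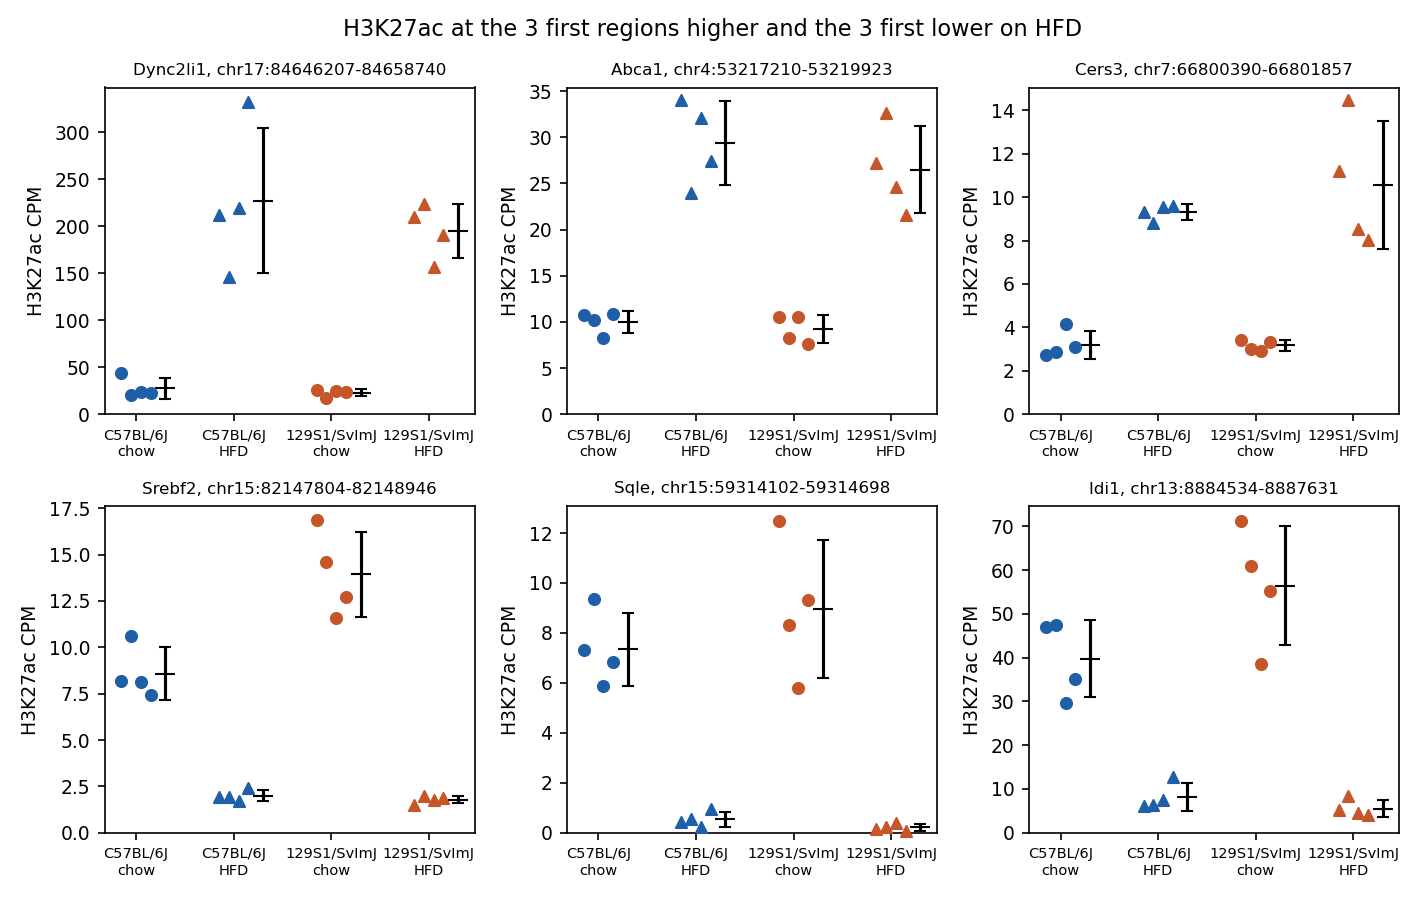
H3K27ac CPM per library at the 3 regions first by p among those higher on HFD (Dync2li1, Abca1, Cers3) and the 3 first among those lower (Srebf2, Sqle, Idi1), by strain and diet, with mean and SD (n = 4 libraries per group) and axes that start at 0. At Dync2li1 the 8 chow libraries average 25.3 CPM and the 8 HFD libraries 211, and at Sqle 8.16 and 0.384.

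By gene list, cholesterol synthesis and uptake fell most: of 190 tested regions near 25 genes, 91 fell and 4 rose, and 112 passed when adjusted over the list alone. Regions of 19 of these genes moved only down. The median log2 change of the list was -0.58, the camera test gave adjusted p = 2.33e-36, and adjusted p = 0.0195 with an estimated correlation. The mean log2 CPM of the list differed by -0.76 (HFD minus chow, n = 8 each; exact permutation of diet within strain, p = 0.000408, the smallest this test can give; adjusted p = 0.0034 over 25 lists). The lipid droplet and lipid uptake list had 39 regions higher and 4 lower of 178 (58 adjusted over the list alone). The camera test gave that list adjusted p = 1.31e-08, but adjusted p = 0.086 with an estimated correlation, and its mean differed by 0.31 (exact permutation, adjusted p = 0.0034). Within it, a region in the fatty acid transporter gene Cd36 (chromosome 5, 17880024 to 17882055) rose 3.11-fold and one in Mogat1, a monoacylglycerol acyltransferase (chromosome 1, 78602232 to 78602612), rose 3.46-fold, and their adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 2.04e-07 and 1.06e-05. Fatty acid and triglyceride synthesis had 84 lower and 30 higher regions of 428 (camera adjusted p = 2.86e-07; adjusted p = 0.273 with an estimated correlation; 148 adjusted over the list alone). Its first genes by p went opposite ways: a region in Acss2, an acetyl-CoA synthetase, fell 2.90-fold, and a region 13972 bp from Scd1, the stearoyl-CoA desaturase, rose 4.53-fold.

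Gluconeogenesis and insulin response genes had 92 lower and 32 higher regions of 546 (camera adjusted p = 0.00051; adjusted p = 0.305 with an estimated correlation; 148 adjusted over the list alone). A region in Irs2, an insulin receptor substrate (chromosome 8, 11002343 to 11004553), fell 2.06-fold, and one 17790 bp from Foxo1, a transcription factor that insulin restrains (chromosome 3, 52367899 to 52369057), rose 1.87-fold. Wnt and TCF7L2 target genes had 29 lower and 9 higher of 414 (camera adjusted p = 0.00382; adjusted p = 0.273 with an estimated correlation; 34 adjusted over the list alone), among them regions 63489 bp from the Wnt receptor gene Fzd7 (3.61-fold lower) and 13399 bp from Tcf7l1 (3.16-fold lower). Male-biased liver genes had 47 lower and 3 higher of 299 (camera adjusted p = 4.23e-08; adjusted p = 0.478 with an estimated correlation; 69 adjusted over the list alone), with Susd4 2.56-fold and the complement gene C8b 1.50-fold lower. The share of regions called was 9.179% for Wnt targets, below the 10.95% of all tested regions. It was 22.71% for gluconeogenesis and 16.72% for male-biased genes. Mean list values differed by -0.12 for gluconeogenesis, -0.09 for Wnt targets and -0.18 for fatty acid synthesis (exact permutation, n = 8 each, adjusted p = 0.0187, 0.0102 and 0.0409), and by -0.24 for male-biased genes (exact permutation, adjusted p = 0.0695, not past the threshold).

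Camera at the preset correlation called marker lists of several cell types for diet, none of them with an estimated correlation. The share of regions called was 14.35% for macrophage and 25% for neutrophil genes, against 10.95% of all regions. It was lower for lymphocyte (8.046%), sinusoidal endothelial (7.109%), hepatocyte identity (6.633%) and periportal genes (8.683%). By exact permutation of diet within strain, the sinusoidal endothelial, hepatocyte identity and periportal lists did not pass (adjusted p = 0.307, 0.165 and 0.0695). The macrophage and Kupffer cell list had 30 regions higher and 2 lower of 223 (median log2 change 0.38; camera adjusted p = 2.70e-12; adjusted p = 0.381 with an estimated correlation; 50 adjusted over the list alone). In it, the region of Spi1, a master regulator of myeloid cells (chromosome 2, 91109049 to 91110727), rose 1.59-fold and that of the chemokine receptor gene Cx3cr1 (chromosome 9, 120048157 to 120049107) fell 1.59-fold. Higher signal was also called for the lymphocyte list (6 higher, 1 lower of 87; 4 adjusted over the list alone), the neutrophil list (3 and 0 of 12; 4) and the sinusoidal endothelial list (25 and 5 of 422; 10). The neutrophil regions lay near 4 of the 14 genes of that list, and the 3 called were all near 1 gene, Elane. Camera gave these 3 lists adjusted p = 0.003, 0.003 and 0.0238, and adjusted p = 0.381, 0.086 and 0.735 with an estimated correlation. Examples were the B cell kinase gene Blk (1.72-fold higher), Cd4 (1.65-fold), neutrophil elastase Elane (1.80-fold) and the scavenger receptor gene Stab2 (1.68-fold), while the endothelial adhesion gene Pecam1 was 2.63-fold lower. The calls at Blk and Cd4 were lost without the 8 mice that also gave TCF7L2 libraries (adjusted p = 0.318 and 0.0644 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Hepatocyte identity genes (30 lower, 9 higher of 588; 30 adjusted over the list alone) and periportal genes (24 and 7 of 357; 29) were called lower (camera adjusted p = 0.000135 and 8.99e-07; adjusted p = 0.478 and 0.4 with an estimated correlation). Of these, Asgr2, an asialoglycoprotein receptor gene, fell 1.86-fold, Acly, the ATP citrate lyase gene, 2.34-fold and Cdh1, the E-cadherin gene, 2.11-fold, while a region 20796 bp from Apob, the main apolipoprotein of very-low-density lipoprotein, rose 1.94-fold.

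Camera passed 12 of 25 lists for diet, 1 of them with an estimated correlation, and 16 with regions within 10 kb of a gene. In 16 of 40 splits of the 16 libraries, the real one included, camera called at least 12 lists, so the number of lists by itself does not set diet apart from other splits. The exact permutation of diet within strain, which uses the spread between mice, passed 9 of 25 lists after adjustment: cholesterol synthesis, lipid droplet and neutrophil (adjusted p = 0.0034 each), Wnt targets, gluconeogenesis, cell cycle (0.0187), macrophage (0.0321), fatty acid synthesis and lymphocyte (0.0489; n = 8 per diet). The other 13 lists, cell cycle among them, did not pass camera. Of these, fatty acid oxidation and PPARa targets had 41 regions higher and 15 lower of 386, stellate cell and fibrosis 2 and 3 of 305, and pericentral hepatocyte 24 and 26 of 308, with a median log2 change of 0.01 and a camera direction below 0. The nearest regions of Tcf7l2 (log2 change -0.15 ± 0.11, SE), Axin2 (0.00 ± 0.17), Glul (0.21 ± 0.18), Lgr5 (-0.20 ± 0.12), Cyp2e1 (0.01 ± 0.14) and Nnt (-0.18 ± 0.11) did not pass the diet test, but other regions of Tcf7l2 (1 higher and 4 lower of 50), Glul (1 higher of 20) and Nnt (1 higher of 8) did. Among these were regions inside Tcf7l2 (-0.71 ± 0.12), inside Nnt (0.69 ± 0.12) and 8964 bp from Glul (1.21, SE 0.155). Their adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 0.000232, 0.00044 and 1.11e-05, and at most 0.00177 with 1 library left out. In a fit of C57BL/6J alone, the Tcf7l2 and Nnt regions did not pass (adjusted p = 0.05735 and 0.164 by that test) and the Glul region did (0.02028). In 129S1/SvImJ alone, the Tcf7l2, Nnt and Glul regions passed (0.003322, 0.0005349 and 0.0004904).

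**Figure D3:**
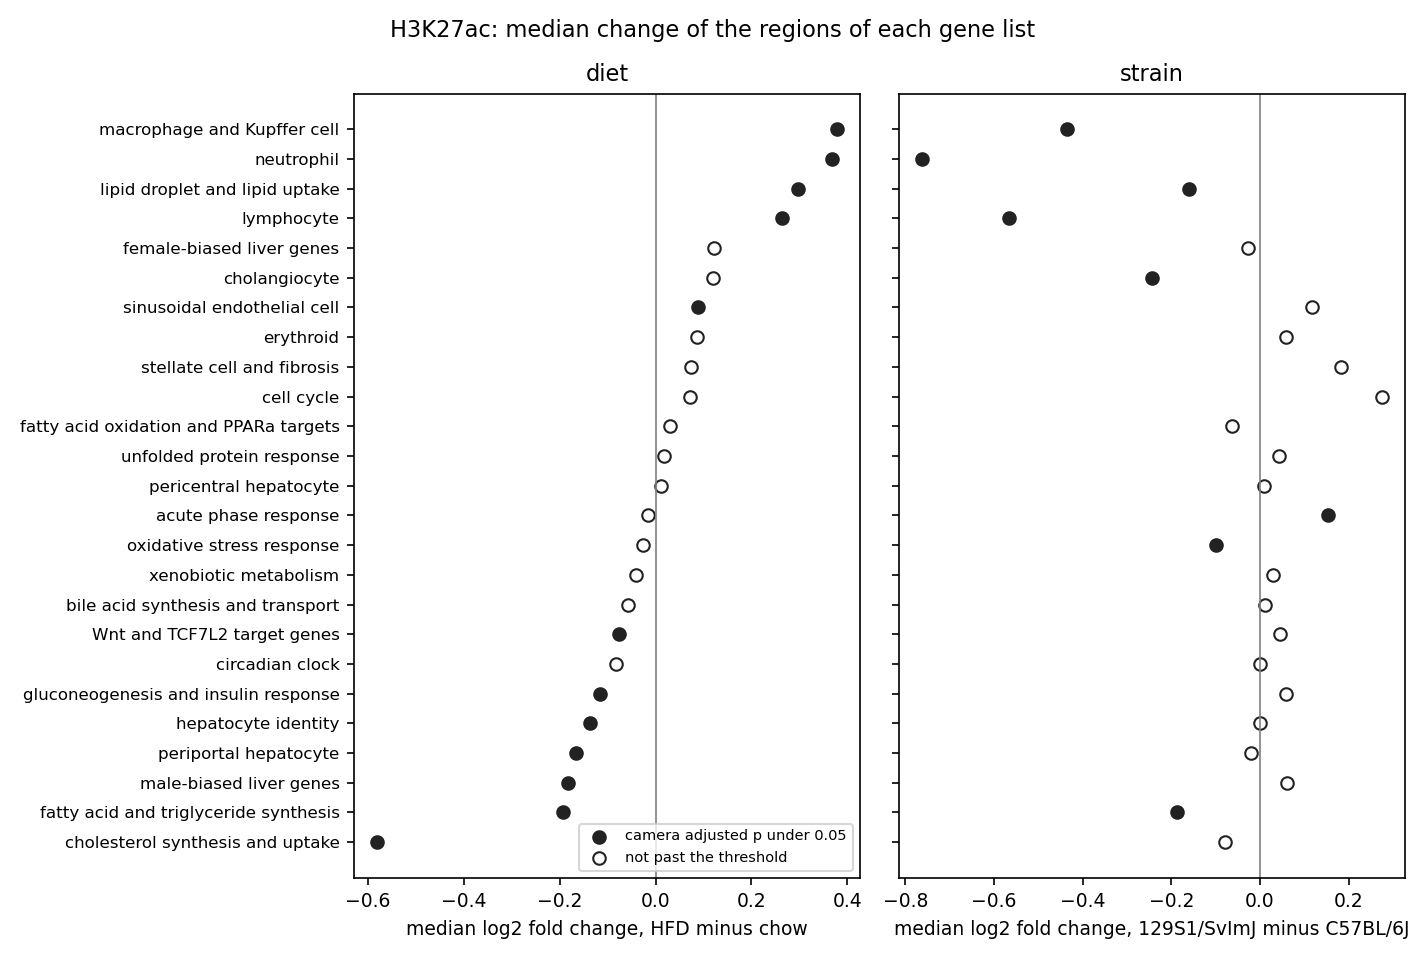
Median log2 change of the tested H3K27ac regions of each of the 25 gene lists for diet (left) and strain (right), with filled points for lists past the camera threshold at the preset correlation and no error drawn. Cholesterol synthesis and uptake lies lowest for diet, at -0.58, and the macrophage list highest, at 0.38.

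Within C57BL/6J, 1881 regions rose and 1023 fell on HFD, and within 129S1/SvImJ 2424 rose and 2938 fell (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 4 libraries per group). At the cholesterol genes the log2 change had the same sign in both strains: -2.40 in C57BL/6J and -4.13 in 129S1/SvImJ at Fdft1, -1.81 and -3.24 at Cyp51, -3.72 and -5.36 at Sqle and -1.41 and -2.56 at Hmgcs1. The difference between strains did not pass at any of these 4 genes (adjusted p between 0.148 and 0.578 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Over all regions the diet effect differed between strains at 3 of 111812, with 6467 at an unadjusted p under 0.05 and 165 by DESeq2. At Erbb4, a receptor tyrosine kinase gene (chromosome 1, 68977471 to 68980034), CPM went from 53.3 to 59.9 in C57BL/6J and from 3.00 to 9.18 in 129S1/SvImJ (difference of log2 changes 1.44 ± 0.23, SE, adjusted p = 0.0426). Near the phospholipase gene Ddhd1 (chromosome 14, 45707077 to 45708284) CPM went from 14.7 to 19.9 and from 8.49 to 3.88 (-1.56 ± 0.23, adjusted p = 0.0296), and at the kinase gene Stk38l (chromosome 6, 146750801 to 146752678) from 12.4 to 8.53 and from 14.7 to 0.877 (-3.51 ± 0.55, adjusted p = 0.0426; all 3 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 4 per group).

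These counts rested on single libraries. The C57BL/6J count was 1517, 1525, 1546 and 1822 without HFD replicate 2, HFD replicate 1, chow replicate 2 and chow replicate 1, 5173 without HFD replicate 4, 1386 in a fit of C57BL/6J alone and 1568 without the mice that gave TCF7L2 libraries. The 129S1/SvImJ count was 2558, 3084 and 2932 without chow replicate 1, chow replicate 2 and HFD replicate 4, and 2013 without the TCF7L2 mice. Without TMM scaling the 129S1/SvImJ split was 3293 higher and 2174 lower, with a median log2 change of 0.13. The 3 regions whose diet effect differed by strain became 39 without C57BL/6J HFD replicate 4, 31 without 129S1/SvImJ chow replicate 4 and 10 without C57BL/6J HFD replicate 3, and without 129S1/SvImJ HFD replicate 3 and chow replicate 3 they were 7 and 6. There were 0 without C57BL/6J chow replicates 2 or 4, 129S1/SvImJ chow replicate 1 or 129S1/SvImJ HFD replicates 2 or 4. With 1 of C57BL/6J chow replicates 1 and 3, C57BL/6J HFD replicate 1, 129S1/SvImJ chow replicate 2 and 129S1/SvImJ HFD replicate 1 left out, the count was 1. None of the 3 regions passed without the 8 mice that gave TCF7L2 libraries (adjusted p = 0.456 at Erbb4, 0.590 at Ddhd1 and 0.0508 at Stk38l by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In simulated data of this design, 4.48% of 2-fold and 63.6% of 4-fold differences between the diet effects were recovered. In the same simulated data 7 unchanged regions were called falsely, more than the 3 called in the real data.

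Between the strains, H3K27ac differed at 34770 of 111812 regions, or 31.1%, with 16925 higher and 17845 lower in 129S1/SvImJ (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 8 per strain). In Myom2, a sarcomere gene (chromosome 8, 15072590 to 15077117), signal was 0.327 ± 0.190 CPM in C57BL/6J and 93.0 ± 11.8 in 129S1/SvImJ (SD, n = 8 each; 294-fold). Other regions higher in 129S1/SvImJ lay 677 bp from the Sin3 corepressor gene Suds3 (chromosome 5, 117084116 to 117091001; 111-fold), in Smco2 (chromosome 6, 146853439 to 146855420; 185-fold), 4885 bp from the fatty acid elongase gene Elovl7 (chromosome 13, 108291994 to 108293974; 230.2-fold), in Usp53 (chromosome 3, 122964994 to 122967743; 39.8-fold) and 883 bp from the collagen gene Col17a1 (chromosome 19, 47692925 to 47694275; 229-fold). Lower in 129S1/SvImJ were regions in the nucleoside transporter gene Slc28a1 (chromosome 7, 81164621 to 81167538; 81.4-fold), 31839 bp from the hypoxia factor gene Hif1a (chromosome 12, 73867328 to 73869485; 38.7-fold), in the kinetochore gene Cenpl (chromosome 1, 161074886 to 161077077; 38.1-fold), in Wdfy4 (chromosome 14, 33071911 to 33073794; 137-fold) and in the cadherin gene Cdh18, from 81.1 ± 6.64 to 0.345 ± 0.220 CPM (chromosome 15, 22789839 to 22793006; 238-fold). A region 22676 bp from Mup18 was 416-fold lower, a value that is uncertain because major urinary protein genes are near-identical copies. Adjusted p in these 12 regions ran from 6.43e-22 to 2.37e-21 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with standard errors of 0.12 to 0.19 on the log2 scale. The libraries of the strains did not overlap in them, which was a condition of their choice.

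The regions of largest fold had almost no reads in one strain. How reads of 129S1/SvImJ were placed on mm10 is not given in the sources used here, so these folds are uncertain. Against 8 129S1/SvImJ libraries at 0, and a floor of 3 reads over the group, a region 2216 bp from Trim5 (chromosome 7, 104290470 to 104291680) was at least 497-fold higher in C57BL/6J and one 4176 bp from Cyp2b9 (chromosome 7, 26168503 to 26169174) at least 342-fold. With 1 to 3 reads in the lower strain, ratios with 95% counting intervals were 1720.0 (308 to 67800.0) near Gm1988, 1400.0 (250.0 to 55200.0) near the sulfotransferase gene Ust and 433 (120.0 to 3580.0) near Gm6866, all higher in 129S1/SvImJ, and 1660.0 (297 to 65600.0) near Mup18, higher in C57BL/6J. Trim5, Cyp2b9 and Mup18 belong to multigene families and their values are uncertain.

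By gene list, camera called 8 of 25 for strain at the preset correlation and 0 with an estimated one. The macrophage and Kupffer cell list had 82 regions lower and 14 higher in 129S1/SvImJ of 223 (median log2 difference -0.44), and the lymphocyte list 41 and 7 of 87 (-0.57). Among them, a region 4413 bp from the integrin gene Itgam (chromosome 7, 128056188 to 128058227) was 32.1-fold lower, one near the chemokine gene Ccl2 2.17-fold lower and one near the B cell factor gene Ikzf3 3.31-fold lower. A region near Klrb1c, of a multigene family and uncertain, was 3.11-fold higher. The neutrophil list had 7 lower and 1 higher of 12: Elane was 1.89-fold lower, while the region 3344 bp from the myeloperoxidase gene Mpo was 77.6-fold higher. Cholangiocyte genes were called lower (28 lower, 10 higher of 102; adjusted p = 0.909 with an estimated correlation), among them Sox9 (4.48-fold) and Pkhd1 (2.10-fold).

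Of the metabolic lists, fatty acid and triglyceride synthesis had 109 lower and 46 higher regions of 428, lipid droplet and lipid uptake 68 and 21 of 178, and oxidative stress response 42 and 8 of 181. A region in Acacb, an acetyl-CoA carboxylase gene (chromosome 5, 114180947 to 114182587), was 8.76-fold lower and one in Lpin1, a phosphatidic acid phosphatase gene (chromosome 12, 16607927 to 16610504), 16.9-fold higher. Cd36 was 2.62-fold lower, a region 47616 bp from the monoglyceride lipase gene Mgll 8.16-fold higher, and the glutathione reductase gene Gsr 17.2-fold lower. A region 8915 bp from Nnt, a mitochondrial transhydrogenase gene (chromosome 13, 119418172 to 119419023), was lower by a log2 difference of -1.76 ± 0.12 (SE). The acute phase list was called higher (37 higher, 11 lower of 177; adjusted p = 0.919 with an estimated correlation), with a region near Socs3 20.8-fold higher and Fgl1 3.21-fold lower.

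Camera passed these 8 of 25 lists for strain, with adjusted p from 1.13e-05 (macrophage) to 0.0279 (neutrophil). None passed with an estimated correlation: adjusted p = 0.909 (macrophage), 0.516 (lymphocyte), 0.516 (neutrophil), 0.909 (cholangiocyte), 0.909 (fatty acid synthesis), 0.638 (lipid droplet), 0.638 (oxidative stress) and 0.919 (acute phase). Adjusted over the list alone, the regions called in these lists numbered 110, 54, 9, 39, 161, 94, 48 and 45, in the same order. The share of regions called was 27.62% for oxidative stress and 27.12% for acute phase, below the 31.1% of all tested regions. In the other lists it ran from 36.21% (fatty acid synthesis) to 66.67% (neutrophil). In 23 of 40 splits of the 16 libraries, the real one included, camera called at least 8 lists. For male-biased genes the median (0.06) and mean (-0.80) differed in sign, and the list did not pass. At Axin2 the log2 difference was 0.42 ± 0.17 (SE, adjusted p = 0.0621 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; 0.00772, 0.0329, 0.0331 and 0.0458 without C57BL/6J HFD replicate 3, 129S1/SvImJ chow replicate 4, HFD replicate 1 and HFD replicate 4, and 0.0482 with a replicate block). It did not pass, and nor did the nearest regions of Nnt (-0.26 ± 0.11; adjusted p = 0.0825, 0.0444 and 0.0382 without C57BL/6J or 129S1/SvImJ HFD replicate 2, 0.0407 without TMM scaling and 0.0488 with loess offsets), Glul (0.32 ± 0.18), Lgr5 (-0.19 ± 0.12), Cyp2e1 (0.17 ± 0.14) and Tcf7l2 (0.04 ± 0.11). Over all regions of these genes, the counts called higher and lower in 129S1/SvImJ were 13 and 1 of 50 for Tcf7l2, 9 and 0 of 17 for Cyp2e1, 2 and 3 of 20 for Glul, 0 and 3 of 4 for Lgr5, 1 and 5 of 8 for Nnt and 0 of 9 for Axin2. In a fit without the 8 mice that gave TCF7L2 libraries 18362 regions were called.

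Regions called for strain were spread unevenly along the autosomes. In 1534 bins of 1 Mb with at least 20 tested regions, the variance of the called share between bins was 6.51 times that of calls shuffled over regions, and the highest of 200 shufflings reached 1.07. In the 387 bins with the highest share, from 40.7% of regions called, 95.6% of bins held regions of both directions. With calls split almost evenly between directions, most bins with this many calls would hold both if directions fell at random. That share thus does not tell whether the regions of a bin move together.

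**Figure D4:**
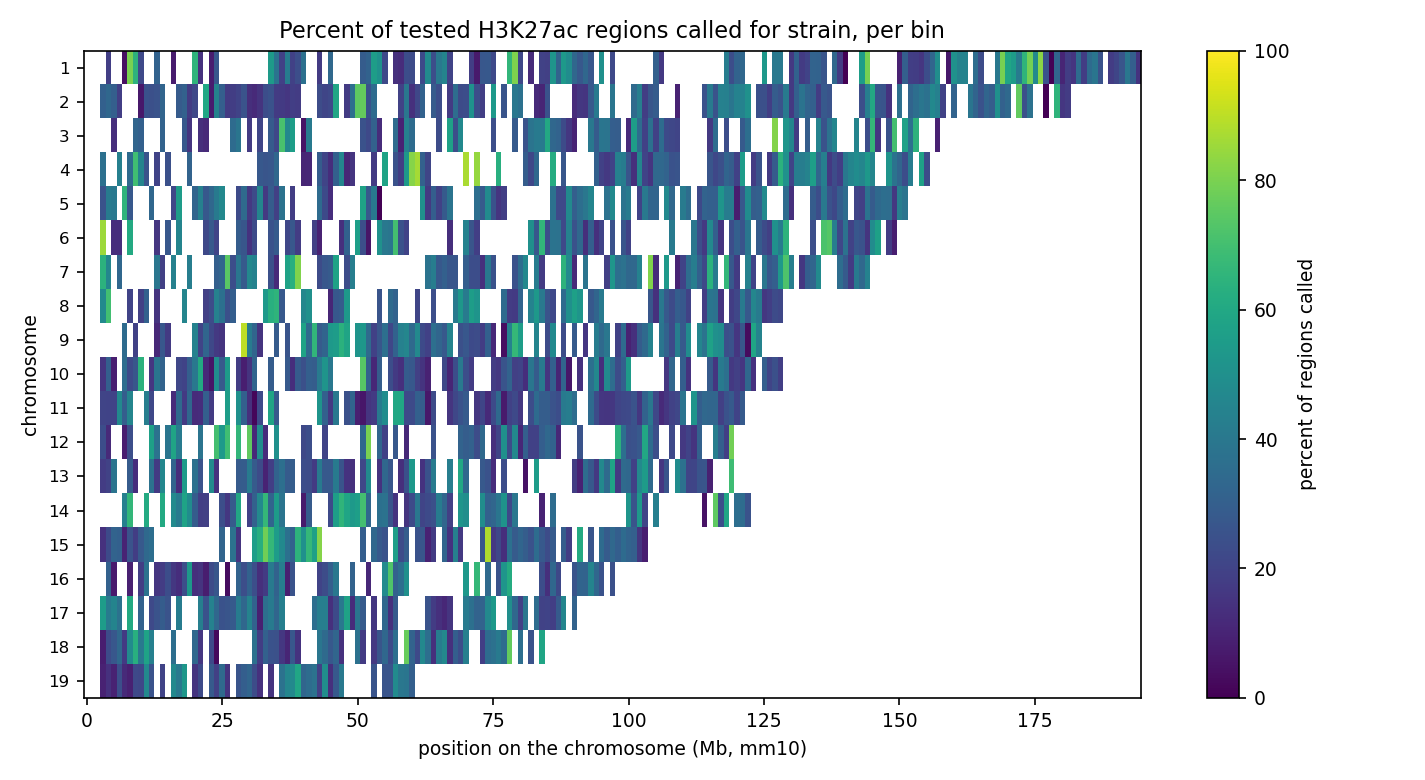
Share of tested H3K27ac regions called for strain in bins of 1 Mb along chromosomes 1 to 19 (mm10), with colour from 0 to 100% and bins of fewer than 20 tested regions left white. Bins of high and low share alternate along the chromosomes, and the variance between bins is 6.51 times that of shuffled calls.

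TCF7L2 binding differed between the strains at 1519 of 11318 tested regions, 704 higher and 815 lower in 129S1/SvImJ (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 4 per strain). A region in Pebp1, a kinase inhibitor gene (chromosome 5, 117285176 to 117285570), held 13.1 ± 2.40 CPM in C57BL/6J and 308 ± 53.7 in 129S1/SvImJ (SD, n = 4 each), or 22.5-fold. Higher binding in 129S1/SvImJ was also found 82383 bp from Slc35b3 (chromosome 13, 38849550 to 38849749; 18.2-fold), 12055 bp from Eri1 (chromosome 8, 35453011 to 35453210; 11.1-fold), in the autophagy gene Uvrag (chromosome 7, 99089695 to 99090031; 9.87-fold), in Nav1 (chromosome 1, 135475023 to 135475478; 34.7-fold) and in Ldlrad4 (chromosome 18, 68008365 to 68008564; 79.8-fold). Lower binding was found near Pithd1 (chromosome 4, 135995125 to 135995324; 84.2-fold), 77771 bp from the mitochondrial carrier gene Slc25a36 (chromosome 9, 97188812 to 97189011; 8.98-fold), in Timmdc1 (chromosome 16, 38522765 to 38522964; 25.9-fold) and in Ablim1 (chromosome 19, 57112928 to 57113127; 8.04-fold). All 4 129S1/SvImJ libraries were at 0 near Klrb1a (chromosome 6, 128631656 to 128631855), near Cyp2b10 (chromosome 7, 25987092 to 25987291) and in Cyp2b13 (chromosome 7, 26087361 to 26087697), so that C57BL/6J was at least 171-fold, 75.4-fold and 49.1-fold higher against a floor of 3 reads over the group. These 3 genes belong to multigene families and are uncertain. With 1 read over the 4 C57BL/6J libraries, the ratio was 58.6 (10.2 to 2350.0, 95% counting interval) near Ust, and 51.7 (8.93 to 2080.0) near Eml4, both higher in 129S1/SvImJ.

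From each fixed gene list with a region called for TCF7L2 strain, the first gene by p follows. Such a choice gives a gene per list by construction. In lipid metabolism, binding was higher in 129S1/SvImJ near Ppara, the nuclear receptor of fatty acid oxidation (5.54-fold), and in Lpin1 (5.21-fold), and lower near the sterol desaturase gene Sc5d (23.4-fold) and in Mogat1 (7.34-fold). In the Wnt list, a region in Lgr4, an R-spondin receptor gene (chromosome 2, 109927484 to 109927683), was 16.6-fold higher. Among the zone markers, Cps1, a periportal urea cycle gene, was 5.31-fold higher and a region near Aldh1a1, a pericentral retinal dehydrogenase gene, 7.88-fold lower. Higher binding was called for regions near Onecut1 (2.86-fold), Apcs (5.73-fold), Ppp1r3b (1.85-fold), Cyp7b1 (2.33-fold) and in Reln (10.2-fold), and lower binding for Creld2 (2.44-fold), Sox9 (2.16-fold) and Rora (1.62-fold). Klrb1c (1.59-fold lower) and Mup11 (4.88-fold higher) belong to multigene families and are uncertain. Standard errors of these log2 differences ran from 0.16 to 0.57 (n = 4 per strain). In Lgr5 binding was 1.39-fold lower (adjusted p = 0.033 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), while Tcf7l2 (-0.12 ± 0.16, SE), Axin2 (-0.17 ± 0.16), Glul (0.52 ± 0.32), Cyp2e1 (0.30 ± 0.16; adjusted p = 0.00357 with loess offsets) and Nnt (-0.01 ± 0.39) did not pass. The Lgr5 call was lost by DESeq2 (adjusted p = 0.141) and with loess offsets (0.0847), and the Cyp7b1 call by DESeq2 (0.223). The Lgr5 call was also lost without C57BL/6J chow or HFD replicate 1 (adjusted p = 0.0879 and 0.205) and without 129S1/SvImJ chow or HFD replicate 2 (0.168 and 0.170), and the Cyp7b1 call without 129S1/SvImJ chow or HFD replicate 2 (0.552 and 0.0719).

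No list passed camera for TCF7L2 strain differences, of 21 with at least 5 regions. The hepatocyte identity list came nearest, with 10 regions higher and 2 lower of 94 (camera unadjusted p = 0.0255, adjusted p = 0.535; 12 adjusted over the list alone), and Wnt and TCF7L2 targets had 8 lower and 2 higher of 71 (adjusted p = 0.674; 10 adjusted over the list alone). DESeq2 called 578 regions for strain, 241 higher and 337 lower. Without C57BL/6J HFD replicate 1, which stood apart on the second component, 1380 regions were called.

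Between the diets, TCF7L2 binding passed the threshold at 3 of 11318 regions (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 4 per diet). In 5 of 34 splits of the 8 libraries, the real one included, at least 3 regions passed, so the count does not set diet apart from other splits. A region 58991 bp from Abca1 (chromosome 4, 53218979 to 53219178), which lies inside the H3K27ac region that rose on HFD, went from 79.8 ± 29.2 to 218 ± 71.3 CPM (SD, n = 4 each; 2.54-fold; adjusted p = 0.00102). A region 40624 bp from the transcription factor gene Zeb1 (chromosome 18, 5816092 to 5816387) rose by 1.49 ± 0.31 on the log2 scale (SE, adjusted p = 0.028), and one 13729 bp from Zfp280d (chromosome 9, 72260574 to 72260889) fell 2.00-fold (adjusted p = 0.0131; all 3 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). At the genes fixed beforehand, the log2 change on HFD was 0.02 ± 0.16 (SE) at Tcf7l2, 0.18 ± 0.16 at Axin2, 0.03 ± 0.16 at Lgr5, 0.15 ± 0.16 at Cyp2e1, -0.79 ± 0.32 at Glul and 0.26 ± 0.42 at Nnt, and none passed. At an unadjusted p under 0.05 there were 884 regions, and DESeq2 called 0. No gene list passed (21 tested); the closest was female-biased liver genes (camera unadjusted p = 0.00571, adjusted p = 0.12). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 regions were called within C57BL/6J, 0 within 129S1/SvImJ and 0 for the difference between strains, against 519, 781 and 457 at an unadjusted p under 0.05 and 0 by DESeq2 in each. The diet count was 19 without C57BL/6J HFD replicate 2, 11 without C57BL/6J HFD replicate 1, 6 without 129S1/SvImJ chow replicate 2, and 1 without C57BL/6J chow replicate 2, 129S1/SvImJ chow replicate 1 or 129S1/SvImJ HFD replicate 2. The count within C57BL/6J was 16 without C57BL/6J HFD replicate 2, 2 without C57BL/6J HFD replicate 1 and 1 without C57BL/6J chow replicate 2, either 129S1/SvImJ chow library or 129S1/SvImJ HFD replicate 2. Within 129S1/SvImJ it was 3 without either of its chow libraries and 2 without its HFD replicate 1, and the difference between strains gave 1 without either C57BL/6J HFD library or 129S1/SvImJ chow replicate 2. The Zeb1 call was lost without C57BL/6J chow replicate 2, C57BL/6J HFD replicate 1, 129S1/SvImJ chow replicate 1 or 129S1/SvImJ HFD replicate 2 (adjusted p = 0.269, 0.144, 0.102 and 0.468 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The Zfp280d call was lost without C57BL/6J chow replicate 2, 129S1/SvImJ chow replicate 1 or 129S1/SvImJ HFD replicate 2 (0.0945, 0.103 and 0.340). With this depth and 2 libraries per group, 41.8% of simulated 2-fold and 2.99% of 1.5-fold diet changes were recovered.

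Strain differences in TCF7L2 binding and in H3K27ac were correlated, and most TCF7L2 regions called for strain had the same sign in both. Across 9695 TCF7L2 regions that overlapped an H3K27ac region, the Spearman correlation of the strain log2 differences was 0.367, and 0.296 with the H3K27ac differences taken from the 8 mice without TCF7L2 libraries. It is a correlation across regions, which are not independent replicates. Of 1145 such TCF7L2 regions called for strain, 919 (80.3%) had H3K27ac differences of the same sign, and where both were called 613 of 663 (92.5%) did. H3K27ac was called at 57.9% of TCF7L2 regions that were called and at 27.1% of those that were not. For diet the correlation was 0.244, and 0.218 with the other 8 mice.

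CTCF peaks were shared more within a strain than between strains. The mean Jaccard index of peak lists was 0.805 ± 0.0314 for the 12 pairs within a strain and 0.697 ± 0.0245 for the 16 pairs between strains (SD over pairs). The difference of 0.108 was the largest of the 35 splits of 8 libraries into 4 and 4 (exact permutation, two-sided p = 0.02857, the smallest this design allows), and the next split reached 0.0243. By diet the difference was -0.0146 (exact permutation, p = 0.714, n = 4 per diet). Merging the lists gave 82861 regions. Of these, 3181 were called in all 4 129S1/SvImJ libraries and in no C57BL/6J library, 575 the other way round, and 42055 in all 8; the sum of 3756 strain-specific regions stood against at most 169 for any other split (exact permutation, p = 0.02857), and 36 regions were specific to a diet. The 129S1/SvImJ lists were longer (67598 ± 3125 against 52246 ± 571 peaks, SD, n = 4 each), which by itself lowers the sharing between strains.

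**Figure D5:**
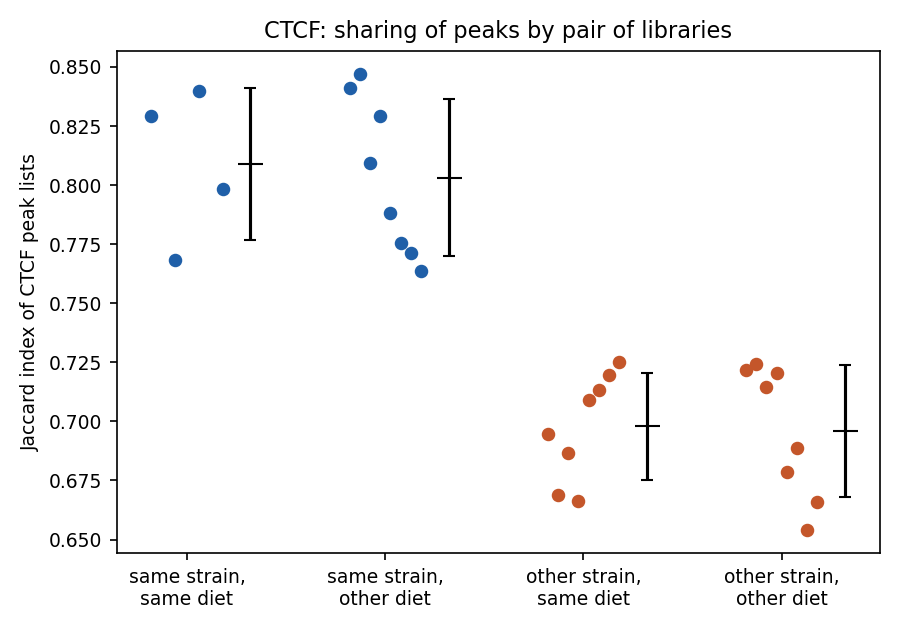
Jaccard index of CTCF peak lists for the 28 pairs of 8 libraries, by whether the pair shares strain and diet, with mean and SD over pairs; the axis does not start at 0. The 12 pairs within a strain average 0.805 and the 16 pairs between strains 0.697.

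Strain-specific CTCF regions coincided with strain differences in H3K27ac. Of 800 tested H3K27ac regions that overlapped a strain-specific CTCF region, 379 (47.4%) were called for strain, against 4448 of 15620 (28.5%) of those that overlapped other CTCF regions (Fisher's exact test, two-sided, odds ratio 2.26, 95% interval 1.95 to 2.62, p = 5.28e-28, with regions as units). At CTCF regions found only in 129S1/SvImJ, 245 of 309 called H3K27ac regions (79.3%) were higher in 129S1/SvImJ, and at those found only in C57BL/6J 51 of 71 (71.8%) were lower in 129S1/SvImJ. Since strain calls cluster along the chromosomes, regions are not independent, and the interval and p of Fisher's test are too narrow. CTCF regions that overlapped no tested H3K27ac region were also strain-specific more often in the 387 bins with the highest share of strain calls. There 6.75% of 12496 were, against 2.97% of 13716 in the 385 bins with the lowest share. How much of the overlap comes from such bins was not tested, nor was a loss of 129S1/SvImJ reads common to both marks.

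The lists of H3K27ac peaks per library were longer in 129S1/SvImJ, with 315439 ± 16649 against 247013 ± 11002 peaks (SD, n = 8 each; exact permutation, two-sided p = 0.000155, the smallest possible). They covered 46.6 ± 2.32 and 36.6 ± 1.57 Mb. Of the consensus peaks of 1 group, 65.6% on average overlapped those of a group of the other strain (8 pairings) and 72.5% those of the other diet in the same strain (4 pairings); there is 1 consensus list per group and no test. These averages rested on the longer 129S1/SvImJ lists. C57BL/6J chow peaks overlapped the other strain at 78.6 and 79.7% and the other diet at 77.1%. For C57BL/6J HFD peaks these were 72.07 and 75.01% and 68.66%. With overlap of at least 50% of both peaks required, the average shares were 39.0% and 51.1%.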

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

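The tests of the macrophage and peak-number patterns and of diet calls in the strain bins were chosen only after the results they bear on had been seen, while the other tests of the 1 Mb bins and those of other splits of the libraries were set before. At Erbb4 the diet effect on H3K27ac differed between the strains by 1.44 on the log2 scale (129S1/SvImJ minus C57BL/6J), at Ddhd1 by -1.56 and at Stk38l by -3.51, each by a test of the difference itself. These 3 regions passed by edgeR with all 16 libraries and TMM scaling; edgeR called 7 without TMM scaling, 7 with loess offsets, 6 without a filter and 15 with a replicate block. Leaving out 1 library ended the Erbb4 call in 12 of 16 cases, all but C57BL/6J HFD replicates 3 and 4, 129S1/SvImJ chow replicate 4 and HFD replicate 3 (log2 differences 1.34 to 1.47 where lost). It ended the Stk38l call in 10, each C57BL/6J chow and 129S1/SvImJ HFD library and 129S1/SvImJ chow replicates 1 and 2 (-3.69 to -3.335), and the Ddhd1 call in 8, C57BL/6J chow replicates 2, 3 and 4, C57BL/6J HFD replicate 1, 129S1/SvImJ chow replicate 1 and 129S1/SvImJ HFD replicates 1, 2 and 4 (-1.62 to -1.48). Without the 8 mice with TCF7L2 libraries none of the 3 passed.

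In 308 groups of 4 libraries, covering 75 named regions and the peak numbers, 24 had 1 library far from the other 3. For independent groups of normally spread values about 15.4 would be flagged. Where the other libraries are at 0, any read is flagged, as near Ust, Gm1988, Mpo and Mup18. The groups also share libraries, so 24 against 15.4 does not show that libraries were unusual. In C57BL/6J on chow, replicate 1 held 43.7 CPM at Dync2li1 (the others 20.4 to 23.7), 0.434 at Myom2 (0.165 to 0.172) and 50.2 at Erbb4 (54.0 to 54.6). Replicate 3 held 42.9 at Acly (74.4 to 78.8), 1.19 at Glul (0.743 to 0.804) and 0.0567 near Ust, where the others were at 0. Replicate 4 held 9.26 in Irs2 (13.2 to 14.0) and 0.0411 near Gm1988 (the others 0), and replicate 2 held 0.517 in Mogat1 (0.864 to 0.929). In C57BL/6J on HFD, replicate 3 held 7.66 CPM in Axin2 (3.87 to 4.24) and 2.47 in Lpin1 (0.391 to 0.617), and its list had 245967 H3K27ac peaks (254688 to 255471). Replicate 2 held 0.424 near Socs3 (0.0558 to 0.112) and 0.606 near Klrb1c (0.279 to 0.302), and replicate 1 held 0.614 in Usp53 (0.664 to 0.673) and 0.0558 near Mpo (the others 0). In 129S1/SvImJ on chow, replicate 1 held 21.5 CPM in Usp53 (25.9 to 26.8), 0.637 in Gsr (0.352 to 0.386) and 1.91 near Klrb1c (0.937 to 1.10). Replicate 2 held 2.82 near Mgll (3.97 to 4.04) and 0.0503 near Mup18 (the others 0), replicate 3 held 1.82 near Pkhd1 (2.97 to 3.09) and replicate 4 held 6.42 near Foxo1 (7.22 to 7.34). In 129S1/SvImJ on HFD, replicate 3 held 49.5 CPM at Fgl1 (the others up to 33.1).

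The H3K27ac regions called for strain were clustered along the chromosomes. Sequence differences between the strains that come in blocks may account for this. Outside such H3K27ac regions, TCF7L2 regions were called for strain at 15.8% of 1347 in the 387 bins with the highest H3K27ac share and at 6.63% of 2263 in the 385 with the lowest, a ratio of 2.39 (95% bootstrap interval 1.88 to 2.95). Lost reads or domains that differ by strain would raise this ratio too, so it does not set sequence blocks apart from them. Reads of 129S1/SvImJ lost where its genome differs from the reference could add to the pattern; 53.8% of calls in the highest bins were lower in 129S1/SvImJ (50.9 to 56.5%), an interval that holds the bound of 55% set beforehand, so this stays open. The same domains moving with strain and with diet are argued against as the whole source: diet calls made up 11.4% of regions in the highest bins and 10.1% in the lowest, a ratio of 1.14 (95% bootstrap interval 1.03 to 1.25). Domains that move together but differ by comparison stay open, since the diet calls were uneven too, with a variance ratio of 3.64 beside 6.51 for strain. No variant calls were used here, so the blocks themselves were not seen.

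The macrophage list was higher on HFD. A lower share of hepatocytes was taken to raise the markers of the other cell types alike. The macrophage list rose more than the stellate list by 0.294 on the log2 scale (exact permutation within strain, p = 0.00735) and more than the cholangiocyte list by 0.296 (exact permutation, p = 0.0453). Regions were given to the nearest gene, so the lists may hold unequal shares of signal from their cell type. Equal rises need not follow, and a lower share of hepatocytes stays open. More macrophages in the HFD livers stays open: 91.5% of the 223 macrophage regions had a change above 0, which restates the rise and decides nothing. A change of state within macrophages was not tested.

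H3K27ac peak lists were longer in 129S1/SvImJ. More regions with signal in that strain stay possible: 48.68% of strain calls were higher there (47.93% without TMM scaling), but both scalings centre the libraries, so this share decides nothing. Deeper 129S1/SvImJ libraries stay possible too: in 41 of 64 pairs of a 129S1/SvImJ and a C57BL/6J library the former had more reads in counted regions, but these are not the sequencing depth, so these explanations cannot be told apart.

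Other splits of the libraries set the real counts beside counts under other labels. The other splits keep the real strain or diet differences, which then add to the spread within groups. Their counts are thus not those expected without any effect. A rank of 1 in 34, 35 or 40 is the strongest result they can give. For H3K27ac, the real split gave the highest count of 40 splits for strain (34770, next 17633) and for diet (12240, next 9186), and of 35 splits for diet in C57BL/6J (2904, next 628) and in 129S1/SvImJ (5362, next 126). For TCF7L2 strain it gave 1524 in a model without the interaction and the highest of the other 33 splits 4, so 1 of 34. Chance cannot be excluded for H3K27ac strain by diet, where 4 of 40 splits gave at least 3 regions and one gave 747. These splits relabel diet within each strain and can carry part of the diet effect into this contrast. What gave the 747 was not tested. Nor can chance be excluded for TCF7L2 diet, where 5 of 34 gave at least 3 and one gave 35. It cannot be excluded for the number of gene lists either: 16 of 40 splits reached the 12 of H3K27ac diet (highest other 17) and 23 of 40 the 8 of H3K27ac strain (16). For TCF7L2 strain and diet 0 lists passed, which all 34 splits reach by construction (highest other 3 and 2), so these counts say nothing about chance.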

How the results depend on the processing

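All alternatives were set before the data were examined. Of 99 values under another setting 81 kept their direction and side of the threshold, or stayed within 1.5 times the count, and of 224 values with 1 library left out 181 did. DESeq2 called 578 regions for TCF7L2 strain and 0 for TCF7L2 diet, and without a filter 1 region was called for TCF7L2 diet in C57BL/6J. Without the 8 mice with TCF7L2 libraries, H3K27ac calls were 18362 for strain, 5970 for diet, 1568 for diet in C57BL/6J and 2013 in 129S1/SvImJ, from fewer samples; C57BL/6J libraries alone gave 1386. H3K27ac strain by diet gave 7 without TMM scaling, 7 with loess offsets, 165 by DESeq2 and 6 without a filter. With an estimated correlation 1 list passed for H3K27ac diet and 0 for strain, and with regions within 10 kb of a gene 16 and 9 did, against 12 and 8. Consensus overlap was 39.0% with 50% of both peaks required. The strain concordance was 0.296 without shared mice and 0.714 over called TCF7L2 regions. The cause of these differences was not tested.

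With 1 library left out, calls ranged from 1032 to 1613 for TCF7L2 strain, 1 to 19 for TCF7L2 diet, 0 to 16 in C57BL/6J, 0 to 3 in 129S1/SvImJ and 0 to 1 for TCF7L2 strain by diet. For H3K27ac they ranged from 32306 to 37407 for strain, 8738 to 15560 for diet, 1517 to 5173 in C57BL/6J, 2558 to 6475 in 129S1/SvImJ and 0 to 39 for strain by diet. Lists numbered 11 to 15 for H3K27ac diet, 7 to 11 for strain and 0 for TCF7L2. CTCF sharing ranged from 0.0971 to 0.125 by strain and -0.0222 to -0.00194 by diet, strain-specific CTCF regions from 4236 to 4968, the difference in peak number from 64657 to 71264, and concordance from 0.328 to 0.371 for strain and 0.182 to 0.260 for diet. Where a group of 2 lost a library, the remaining one was assumed to vary like the other groups.

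Replicate numbers were shared by the groups and were not used as pairs. The middle number of the mouse identifiers differs from the rest of the group for H3K27ac replicate 4 and TCF7L2 replicate 2 in each group, and its meaning is not given in the sources used here. No middle number is shared between groups, so what it marks cannot be fully told apart from strain and diet. Mice of a group that share it were treated as independent. Same-numbered H3K27ac libraries correlated at -0.136 to 0.203 in 24 pairs, 6 of them over 0.1, with 8 of 16 libraries closest to their own number, and TCF7L2 at 0.025 to 0.098 in 12 pairs, with 8 of 8. With 2 TCF7L2 libraries per group, their deviations from the group mean mirror each other. Each TCF7L2 value thus occurs for both replicate numbers, and 8 of 8 follows once all values lie above 0. With the replicate block, 15 H3K27ac regions passed for strain by diet, and no other count of calls moved by over 1.5 times.

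Values that changed sign belonged to regions past no threshold. Log2 values for H3K27ac diet at Axin2 were -0.002 (DESeq2 size factors), -0.002 (DESeq2) and -0.037 (replicate block), and -0.147 to 0.076 with single libraries left out. At Cyp2e1 they were -0.012 (loess), -0.026 (without the TCF7L2 mice) and -0.048 to 0.081 (libraries left out). For H3K27ac strain they were -0.051 at Cyp2e1 (without the TCF7L2 mice) and -0.026 to 0.083 at Tcf7l2 (libraries left out). For TCF7L2 strain they were 0.038 at Tcf7l2 (loess), and at Nnt 0.003 (DESeq2), 0.033 (no TMM), 0.014 (replicate block) and -0.231 to 0.493 (libraries left out). For TCF7L2 diet, with libraries left out, they were -0.066 to 0.097 at Tcf7l2, -0.120 to 0.167 at Lgr5 and -0.275 to 0.442 at Nnt. Among called regions, DESeq2 ended the TCF7L2 diet calls at Abca1, Zeb1 and Zfp280d (adjusted p = 0.196, 1.00 and 1.00) and the TCF7L2 strain calls at Cyp7b1 and Lgr5 (0.223 and 0.141), and loess offsets ended that at Lgr5 (0.0847). Calls were gained for TCF7L2 strain at Cyp2e1 with loess offsets (0.00357), and for H3K27ac strain at Axin2 with the replicate block (0.0482) and at Nnt without TMM scaling (0.0407) and with loess offsets (0.0488).

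Peak scores and a genome were not used here, so stricter peak thresholds and the TCF7L2 motif share were not run, nor fits of a single strain for strain by diet. The diet concordance over called TCF7L2 regions gave no value. For TCF7L2, 2.99% of 1.5-fold diet changes were recovered in simulated data with its depth and 2 libraries per group, which were not varied apart.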

Other observations

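No hypothesis is tested in this part, and the regions and lists below follow the choices set before the data were examined. Of the gene lists that did not pass camera for H3K27ac diet, xenobiotic metabolism had 46 regions lower and 31 higher of 580 on HFD (median log2 change -0.04; camera adjusted p = 0.0823), bile acid synthesis and transport 38 and 21 of 420 (-0.06; 0.0858), and circadian clock genes 4 and 7 of 209 (-0.08; 0.0773). Adjusted over the list alone, 87, 70 and 7 regions were called. Acute phase genes had 10 higher and 14 lower of 177, oxidative stress genes 5 and 11 of 181, unfolded protein response genes 10 and 13 of 192, female-biased genes 9 and 4 of 90, cholangiocyte genes 4 and 6 of 102, cell cycle genes 5 and 0 of 80, and erythroid genes 0 and 1 of 17. Adjusted over the list alone these were 28, 12, 24, 15, 9, 2 and 1. With regions within 10 kb of a gene, xenobiotic metabolism, bile acid and circadian clock genes passed (camera adjusted p = 0.0136 each), as did oxidative stress genes (0.0262). With an estimated correlation, at the main gene distance, camera gave these lists adjusted p = 0.7123, 0.7055, 0.7055 and 0.7123, in the same order. For unfolded protein response genes the median (0.02) and mean (0.02) lay above 0 and the camera direction below, and for erythroid genes the median was 0.09 and the mean -0.03.

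Between the strains, stellate cell and sinusoidal endothelial genes had more H3K27ac regions higher than lower in 129S1/SvImJ, 56 and 31 of 305 and 55 and 20 of 422, while macrophage and lymphocyte genes had more lower. Neither the stellate nor the endothelial list passed (camera adjusted p = 0.0804 and 0.0907), nor did cell cycle genes (20 higher and 8 lower of 80, adjusted p = 0.0907). The stellate list passed camera with regions within 10 kb of a gene (0.0365), but at the main gene distance its adjusted p with an estimated correlation was 0.9194. For bile acid genes (median 0.01, mean -0.10), xenobiotic metabolism (0.03, -0.02) and pericentral hepatocyte genes (0.01, -0.15) the median and mean log2 difference had opposite signs.

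Peaks in the per-library lists of C57BL/6J were all exactly 151 bp wide for H3K27ac and TCF7L2. In 129S1/SvImJ the median was also 151 bp, but widths ran from 116 to 199 bp for H3K27ac and from 130 to 177 bp for TCF7L2; whether this bears on regions with almost no reads in one strain was not tested. In the CTCF lists 27.6 to 39.6% of entries were repeats of another entry of the same list.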
